A study of Mus musculus with 10 samples.

How the data were processed

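RNA from Neuro-2a cells in medium with 2% serum was sequenced on the Ion Proton system after transfection of an siRNA against luciferase (Luc, the control) or Sfpq, per the labels' protocols. Groups and replicate numbers were taken from the sample titles: 3 Luc and 3 Sfpq libraries of poly(A)-selected RNA, and 1 Luc and 1 Sfpq library of RNA depleted of ribosomal RNA. The description of the second Sfpq poly(A) library gives it another replicate number than its title, and the title was used. RNA polymerase II chromatin immunoprecipitation, listed with 1 library per group, is not analysed here.

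The deposited values are RPKM, 1 file per library, with 1 row per RefSeq transcript, per the file headers. Reads were aligned with TopHat2 2.0.10 to the mouse build mm9, per the submitters' processing notes; the program that computed RPKM, its annotation release, its treatment of reads with several matches and any filter are not given in the sources used here. RPKM divides by transcript length and by the library's reads, so it holds no count of reads. Low values of different libraries differed by ratios of small whole numbers times 1 factor, which gave the relative depths in the report; between 71.0% and 82.0% of pairs of low values matched a ratio of whole numbers up to 20 within 0.002 on the natural log scale. No interval or detection limit from read counts can be given. Precision therefore comes from the replicates alone.

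Each file held 30978 rows, of which 30507 (98.5%) were named by matching the RefSeq identifier to a gene table of assembly GRCm38.p6. That assembly differs from the authors' build, so the table served for names only and no coordinates or gene spans were used. The remaining 471 rows kept their identifier. For the 4220 genes with more than 1 row, the row with the highest mean RPKM over all libraries stood for the gene; for Sfpq this was NR_045010. Of 875 symbols written in 19 gene lists, 859 were found.

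Poly(A) libraries were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with a trended prior, for genes with a mean of at least 0.5 RPKM over the 6 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists with at least 5 tested members were tested against all other genes with camera, limma's competitive set test, at a preset correlation between genes of 0.01, adjusted over 18 lists. Of the 18, 11 were called; with the correlation estimated from the data 0 were called, and 1 (oxidative phosphorylation) had an unadjusted p under 0.05. Gaps per library were compared with an exact permutation test. The rRNA-depleted libraries, with 1 per group, were described by log2 ratios on the same scale for genes with a mean of at least 0.5 RPKM over both; a list's median was ranked among 10000 random lists of the same size matched on mean RPKM in 20 bins, as a description of these libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps.

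The comparison of long genes was planned on a genomic span of at least 100 kb. As no annotation of the authors' build was used here, the replacement set for that case was applied: a list of long neuronal genes, written from general knowledge of gene size, with a list of short neuronal genes beside it. No span was measured. The gene lists, the tests of the planned comparisons and the rule for naming genes were fixed before the data were examined. The lists of snoRNA host genes and decay factors, the comparison of long with short neuronal genes and the tests of explanations in the closing section came later. The rule named Sfpq, Nono, Pspc1, Neat1 and Malat1; the 8 largest changes in each direction among called genes with a mean of at least 1 RPKM whose Sfpq libraries all lay on the same side of all Luc libraries; the 3 largest called members of each list, or its 2 most abundant members where none was called; and the 5 largest rRNA-depleted ratios in each direction at a mean of at least 5 RPKM. Every other gene named was chosen after its values were seen, and a few genes, 1 of them under the rule, are not reported here.

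The limma step was tested on simulated data for the poly(A) comparison, with 200 of 11727 genes changed singly and 40 lowered together as a list: 16.4% of changes of 0.5 log2 units were recovered, 74.6% of changes of 1 and 100% of changes of 2, and 0.0348% of unchanged genes were called. Noise was drawn for each gene alone, and far fewer genes were changed than were called in the data, so these shares need not hold there. The random-list ranking was tested on simulated ratios of 11386 genes, where 1 of 20 unchanged lists fell outside the central 95%. Alternatives were other pseudocounts (0.1 and 1), no filter or a minimum mean of 2 RPKM, median-ratio scaling, quantile normalization, limma without trend, a replicate block, an estimated correlation between genes and leaving out each library in turn. The mean of all rows of a gene, and leaving out libraries for the correlation between preparations and for each gene list, were added after the data were seen; for the histone list, what leaving out Luc replicate 3 would show was written down before its value was computed.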

Results

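The series measured RNA in Neuro-2a cells, a mouse neuroblastoma line that can be driven towards a neuron-like state, after small interfering RNA (siRNA) against Sfpq. Sfpq is a nuclear RNA- and DNA-binding protein of the DBHS family, whose other mouse members are Nono and Pspc1. Control cells received an siRNA against luciferase (Luc), a gene that mouse cells lack. Poly(A)-selected RNA was sequenced from 3 Luc and 3 Sfpq libraries, and RNA depleted of ribosomal RNA from 1 library of each kind. The series labels also list RNA polymerase II chromatin immunoprecipitation, which is not analysed here. The values are RPKM (reads per kilobase of transcript, scaled to the size of the library), so the absolute depth is unknown. Steps between low values put the depth of the poly(A) libraries between 0.628 times (Sfpq replicate 1) and 1.28 times (Luc replicate 3) that of Luc replicate 1, and the rRNA-depleted libraries at 2.64 (Luc) and 2.65 (Sfpq) times. Between 10804 and 10949 genes reached 1 RPKM in each poly(A) library. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

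Sfpq RNA was strongly reduced in every Sfpq library. Its RPKM was 56.8, 60.8 and 73.0 in the 3 Luc libraries and 3.98, 4.75 and 6.47 in the 3 Sfpq libraries, which leaves 7.97% of the Luc mean (log2 fold change -3.54, SE 0.17, limma adjusted p = 1.56e-06). In rRNA-depleted RNA it was 30.8 in the Luc and 4.43 in the Sfpq library. The row used for Sfpq, 1 of 2, is a noncoding transcript record. With the mean of all rows of a gene, Sfpq stayed lower (limma adjusted p = 1.62e-06). The relative Pspc1 rose 2.60-fold, from 24.1 ± 3.11 to 63.1 ± 0.978 RPKM (SD, n = 3; limma adjusted p = 2.34e-05), and Nono rose 1.35-fold, from 75.2 ± 13.1 to 101 ± 8.92 RPKM (SD, n = 3; limma adjusted p = 0.0294). Neat1, whose gene makes the RNA scaffold of paraspeckles, fell by 0.82 on the log2 scale in poly(A) RNA (SE 0.23, limma adjusted p = 0.0196). Its log2 ratio in rRNA-depleted RNA was -0.14, with 1 library per group. Neat1 had 1 row, so a fall of the scaffold form itself is not shown. Malat1, another abundant nuclear RNA, had 15.5 ± 2.16 RPKM in Luc and 12.6 ± 4.52 in Sfpq libraries (SD, n = 3), a difference that did not pass the limma test (adjusted p = 0.252). The Nono call ended when Luc replicate 1 (log2 fold change 0.38), Luc replicate 2 (0.34), Sfpq replicate 2 (0.38) or Sfpq replicate 3 (0.41) was left out, and the Neat1 call ended without Luc replicate 1 (-0.77), Sfpq replicate 1 (-0.72) or Sfpq replicate 2 (-0.63). With no filter on low values, neither Nono (limma adjusted p = 0.060) nor Neat1 (0.0647) passed. Without Sfpq replicate 3, Malat1 passed as lower (-0.59).

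**Figure D1:**
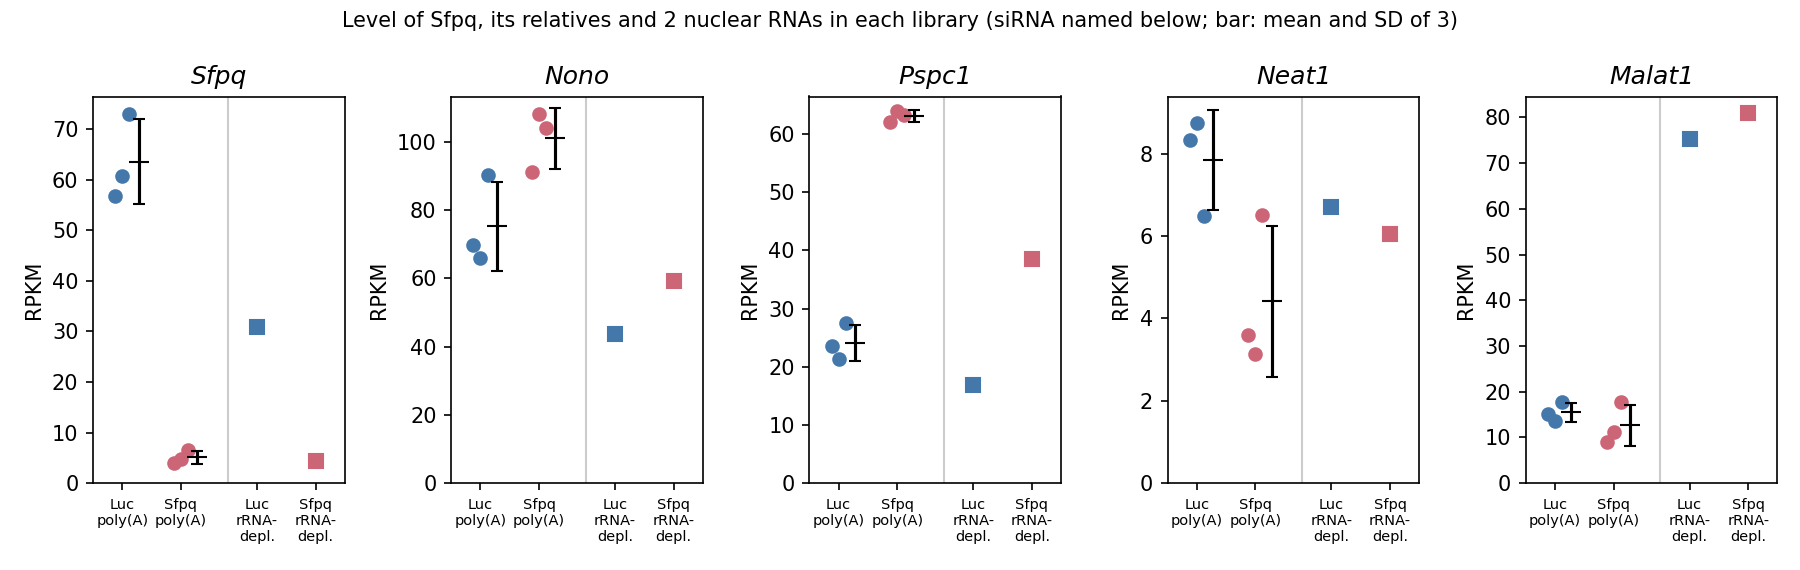
RPKM (vertical axis, from 0) of 5 genes in each library, by siRNA and RNA preparation; circles are poly(A) libraries, black bars their mean and SD of 3 libraries, and squares the single rRNA-depleted libraries. Sfpq fell from 56.8 to 73.0 RPKM in the Luc libraries to 3.98 to 6.47 in the Sfpq libraries, while Pspc1 rose from a mean of 24.1 to 63.1.

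The first comparison asks which transcripts differ when Sfpq is depleted, in poly(A) RNA. Of 11727 genes tested, 2502 rose and 2185 fell (limma, adjusted p under 0.05), and 7040 did not pass. Large changes were more often falls, with 555 genes lower and 270 higher by at least 2-fold, and 89 lower and 8 higher by at least 4-fold. The 3 Sfpq libraries lay wholly above or below the 3 Luc libraries for 52.9% of genes, against 10% by chance. The count of higher genes was 1546 without Sfpq replicate 2 and 1631 without Sfpq replicate 3. Luc replicate 3 stood somewhat apart, with correlations of 0.985 and 0.979 to the other Luc libraries, which correlated at 0.996 with each other; without it 3621 genes were higher and 2645 lower.

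The largest falls were in Slc39a11, a zinc transporter (13.0 ± 1.86 to 0.2995 ± 0.0557 RPKM, SD, n = 3; log2 fold change -4.07), 3110082I17Rik (-4.04) and Ergic1, a protein of the compartment between endoplasmic reticulum and Golgi (-4.01). Vat1l fell from 105 ± 5.67 to 8.38 ± 0.116 RPKM (SD, n = 3; -3.57). Behind Sfpq itself came Tmem150c (-3.38), the mitochondrial enzyme gene Clybl (-3.32) and Rgs7, a regulator of G-protein signalling (-3.31). For these genes the SE lay between 0.09 and 0.17, and limma adjusted p between 1.86e-07 and 1.84e-06. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of genes that end near 0, such as Slc39a11 and Clybl.

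The largest rises were in Grap2, a signalling adaptor best known in T cells (0.468 ± 0.103 to 7.23 ± 0.547 RPKM, SD, n = 3; log2 fold change 3.00), the noncoding RNA 1110038B12Rik (2.32), Mgarp, a mitochondrial protein gene (4.77 ± 0.550 to 25.4 ± 1.71 RPKM, SD, n = 3), and Mrtfb, a coactivator of serum response factor (2.21). Next were the noncoding RNA Chaserr and the row NM_001081005, for which the name tables used here gave no symbol (both 2.17), Taf1d, which encodes a subunit of an RNA polymerase I factor (2.07), and the noncoding RNA Epb41l4aos (2.01). For these genes the SE lay between 0.09 and 0.22, and limma adjusted p between 5.61e-07 and 0.000119. The row used for Taf1d, 1 of 3, is a noncoding transcript record, so the rise is not shown for its coding mRNA alone. Where genes overlap, RPKM values cannot tell their reads apart, which concerns noncoding RNAs such as Epb41l4aos and Chaserr.

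The series title concerns long neuronal genes, and a list of such genes was compared with the rest. Of 45 measured long neuronal genes, 34 fell, 1 rose and 10 did not pass (37 fell and 1 rose when adjusted over the list alone). The adhesion molecule genes Cadm1 (25.8 ± 1.71 to 2.66 ± 0.0517 RPKM, SD, n = 3; log2 fold change -3.05) and Ncam1 (-2.35), the receptor tyrosine kinase gene Alk (-2.29) and the microtubule-binding protein gene Mapt (-2.03) were among those that fell. The list also held falls of the ankyrins Ank2 (-1.07) and Ank3 (-0.89) and of the calcium channel gene Cacna1c (-1.61). The gene that rose was the transcription factor Foxp1 (0.45); 0 rose with limma without Sfpq replicate 2, 2 without Sfpq replicate 1 and 3 without Luc replicate 3. The list's median log2 fold change was -0.89, which is 0.95 below that of the other tested genes (difference -0.95). The list has 124 genes in the files, and with no filter on low values 101 were tested, of which 48 fell and 2 rose, with a median of -0.18. Lower calls made up 75.6% of the list and 18.4% of the other genes (Fisher's exact test, two-sided, p = 1.46e-16; genes are not independent replicates). The list ranked below the other genes with camera, limma's set test (adjusted p = 1.79e-14), but not past the threshold with an estimated correlation between genes (adjusted p = 0.348 with an estimated correlation).

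Treating the library as the unit, the median log2 level of the long list lay 1.04 log2 units below that of the other genes in Luc libraries (gap -1.04 ± 0.0867, SD, n = 3) and further below in Sfpq libraries (-1.91 ± 0.0822, SD, n = 3). All 3 Sfpq gaps (-1.95, -1.96 and -1.81) lay below all 3 Luc gaps (-1.06, -1.11 and -0.94). The difference of -0.87 gave p = 0.1 in a two-sided exact permutation test, which is the smallest p that 3 against 3 libraries allow.

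Short neuronal genes, which encode cytoskeletal, synaptic and secretory proteins, moved less and in both directions. Of 45 measured, 17 fell, 6 rose and 22 did not pass (18 and 6 adjusted over the list alone). Rab3a, a GTPase of synaptic vesicles (-2.35), the neuropeptide precursor gene Vgf (453 ± 96.5 to 131 ± 16.6 RPKM, SD, n = 3; -1.77), Cplx1 (-1.60) and the synapsin gene Syn1 (-1.54) fell, while the secretory granule genes Resp18 (0.78) and Chga (0.75) rose. The median was -0.12, so that long and short neuronal genes differed by -0.78 in their medians (camera p = 0.000234 over both lists; p = 0.196 with an estimated correlation). Against all other genes the short list had a camera adjusted p = 0.0128 (limma), and adjusted p = 0.557 with an estimated correlation; without Luc replicate 2 it was 0.0877. The short list had a median of -0.06 without Luc replicate 2 and -0.18 without Luc replicate 3.

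Axon guidance and adhesion genes fell in 18 of 30 measured cases, with 4 higher and 8 not past the test (20 lower and 5 higher adjusted over the list alone). The netrin receptors Unc5c (-2.11) and Unc5b (-1.63) fell with Ncam1 and the tyrosine kinase gene Fyn (-1.24), whereas Plxnb1 (1.13), Plxna1 (1.10), Cntn2 (1.07) and Plxnd1 (0.75) rose. The list's median was -0.51 (camera, limma adjusted p = 0.00012; adjusted p = 0.348 with an estimated correlation), and 17 of the genes written in it, tested or not, also belong to the long neuronal list. With no filter on low values, 20 of 51 axon guidance genes fell and the median was -0.07. Genes of sympathetic neuroblast identity, the lineage of neuroblastoma, fell in 12 and rose in 6 of 25 cases, with 7 not past the test (13 and 6 adjusted over the list alone). Alk, the RNA-binding protein gene Elavl4 (-1.90), the oncogene Mycn (8.43 ± 1.15 to 2.92 ± 0.387 RPKM, SD, n = 3; -1.38), and the transcription factors Isl1 (-1.13) and Hand2 (-0.72) fell, while the noradrenaline-synthesis gene Dbh (0.54) and Gata3 (0.51) rose. The median was -0.38 (camera, limma adjusted p = 0.021; adjusted p = 0.506 with an estimated correlation; 0.0657 without Luc replicate 2, where the median was -0.24), and 3 of the list rose without Sfpq replicate 2.

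Genes of the cell cycle and of DNA repair rose more often than they fell. In the cell cycle list 20 of 52 rose, 3 fell and 29 did not pass (23 and 3 adjusted over the list alone), with a median of 0.27 (camera, limma adjusted p = 0.00341; adjusted p = 0.359 with an estimated correlation). The replication helicase subunit Mcm3 (1.08), the kinase Cdk2 (0.82) and the cyclin Ccnd3 (0.76) rose, and the cyclins Ccna2 (-0.66) and Ccnd1 (-0.41) and the proliferation marker Mki67 (-0.52) fell. The DNA repair list had 20 of 43 higher, 3 lower and 20 not past the test (23 and 4 adjusted over the list alone), with a median of 0.36 (camera, limma adjusted p = 0.000595; adjusted p = 0.506 with an estimated correlation). The Fanconi anaemia genes Fanci (1.02) and Fanca (0.90) and the tumour suppressor gene Brca1 (0.76) rose, whereas the end-joining gene Xrcc4 (-1.23), Parp1 (-0.61) and Rif1 (-0.58) fell. Without Sfpq replicate 2, 11 cell cycle genes rose, and without Luc replicate 3, 30 rose. The falls among cell cycle genes numbered 1 without Sfpq replicate 1 and 5 without Luc replicate 3.

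Replication-dependent histone genes, whose mature mRNAs mostly lack a poly(A) tail, had 12 of 59 members higher and 0 lower in poly(A) RNA, with 47 not past the limma test (4 higher and 0 lower adjusted over the list alone; 23 higher and 0 lower at unadjusted p under 0.05). H1f2 rose from 4.03 ± 0.895 to 13.0 ± 2.62 RPKM (SD, n = 3; 1.58), H4c9 by 0.97 and H4c17 by 0.75 on the log2 scale. The list's median of 0.32 (camera, limma adjusted p = 0.00217; adjusted p = 0.597 with an estimated correlation) became 0.17 without Luc replicate 3 (adjusted p = 0.172), and 4 genes were higher without Sfpq replicate 1 and 5 without Sfpq replicate 2. The share of histone genes called higher was near that of all tested genes (2502 of 11727), while 0 lower was below theirs (2185 of 11727). The higher histone genes numbered 6 with median-ratio scaling or quantile normalization and 7 with no filter on low values. With a replicate block they numbered 24 (camera, limma adjusted p = 0.000174), although replicate numbers did not pair all the libraries. Histone genes are near-identical copies, so reads may be split between them; the H4c9 call also ended without Luc replicate 3 (0.61), Sfpq replicate 1 (0.63), Sfpq replicate 2 (1.15) or Sfpq replicate 3 (1.12), and the H4c17 call without Sfpq replicate 1 (0.58) or Sfpq replicate 2 (0.76). Both calls also ended with no filter on low values, median-ratio scaling, quantile normalization or limma without trend, and the H4c9 call with a pseudocount of 0.1.

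Interferon response genes rose in 16 of 33 cases, with 4 lower and 13 not past the test (16 and 4 adjusted over the list alone). Parp9 (1.46), the antiviral enzyme gene Rsad2 (1.58 ± 0.422 to 4.55 ± 0.311 RPKM, SD, n = 3; 1.29), Parp14 (1.19) and the transcription factor Irf7 (1.12) rose, whereas Isg15 (-0.80), Ccl5 (-0.72), Oasl1 (-0.71) and Cxcl10 (-0.39), all classical induced products of the pathway, fell. The median was 0.32 (camera, limma adjusted p = 0.0086; adjusted p = 0.506 with an estimated correlation). Genes of the integrated stress and unfolded protein responses moved the other way, with 17 of 39 lower, 0 higher and 22 not past the limma test (17 and 0 adjusted over the list alone; 21 lower and 0 higher at unadjusted p under 0.05). The stress-induced gene Nupr1 (-1.37), the amino acid transporters Slc7a11 (-1.33) and Slc7a1 (-1.19) and the chaperone Hspa5 (-0.45) fell, while the central factor Atf4 had 589.9 ± 73.2 RPKM in Luc and 571 ± 29.95 in Sfpq libraries (SD, n = 3; limma adjusted p = 0.8002). The median was -0.25 (camera, limma adjusted p = 0.000205; adjusted p = 0.348 with an estimated correlation).

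Oxidative phosphorylation genes had small falls, with 13 of 58 lower, 1 higher (Sdhc, 0.48) and 44 not past the test (7 and 1 adjusted over the list alone). Sdha (-0.73), Ndufa9 (-0.70) and Atp5g3 (-0.62) had the largest, and the median was -0.22 (camera, limma adjusted p = 0.00218; adjusted p = 0.331 with an estimated correlation). Quantile normalization ended that list's call (adjusted p = 0.0844; median -0.11, 7 lower and 2 higher), and the count of lower genes ran from 7 without Sfpq replicate 2 or 3 to 21 without Luc replicate 3 (8 without Luc replicate 1 or Sfpq replicate 1); Atp5g3 did not pass without Sfpq replicate 1 (-0.53). The share of oxidative phosphorylation genes called lower was not far above that of all tested genes (2185 of 11727). The share called higher was below theirs (2502 of 11727). Cholesterol synthesis genes had 6 of 22 lower and 1 higher (Idi1, 0.51), with 15 not past the test (5 and 1 adjusted over the list alone). Dhcr7 (54.5 ± 0.476 to 25.6 ± 1.23 RPKM, SD, n = 3; -1.08) and Insig1 (-0.79) fell. The cholesterol list itself was not called (median -0.11; camera, limma adjusted p = 0.0861), but was called with no filter on low values (adjusted p = 0.0236).

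Transcription elongation factors had 8 of 36 higher, 0 lower and 28 not past the limma test (8 and 0 adjusted over the list alone; 11 higher and 0 lower at unadjusted p under 0.05). Larp7 (0.77), which binds the 7SK RNA, the cyclin Ccnt2 (0.73) and the kinase Cdk12 (0.61) rose, and the list median was 0.18 (camera, limma adjusted p = 0.045; adjusted p = 0.557 with an estimated correlation). That call ended, for example, without Luc replicate 1 (0.0803), Luc replicate 2 (0.0877) or Sfpq replicate 2 (0.0734) and with median-ratio scaling (0.0545); without Luc replicate 3, 14 of these genes rose. The share of elongation factors called higher was near that of all tested genes (2502 of 11727), while 0 lower was below theirs (2185 of 11727). The elongation median lay within the central 95% of random lists matched on expression (-0.12 to 0.21). In rRNA-depleted RNA it was 0.12, also within that range (-0.19 to 0.14). Of 47 splicing factors 13 rose, 3 fell and 31 did not pass (10 and 3 adjusted over the list alone). The splicing regulators Mbnl2 (-1.64), Srrm4 (4.23 ± 0.318 to 1.03 ± 0.0748 RPKM, SD, n = 3; -1.63) and Rbfox2 (-0.37) fell, and Srsf9 (0.89) had the largest rise. The splicing list was not called (median 0.18; camera, limma adjusted p = 0.0674), but was called without Luc replicate 3 (0.00882, with 26 higher) or Sfpq replicate 1 (0.0466), with quantile normalization (0.0159), with a minimum mean of 2 RPKM (0.0495) and with no filter on low values (0.0155). The higher splicing factors numbered 5 without Luc replicate 1, 8 without Luc replicate 2, and 4 without Sfpq replicate 2 or 3.

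The list of DBHS and paraspeckle proteins and RNAs had 11 of 24 higher, 3 lower and 10 not past the test (11 and 3 adjusted over the list alone). Besides Pspc1 and Nono, Rnf112 (1.31), Rbmx (0.95) and Tardbp (0.84) rose, and Sfpq, Neat1 and Taf15 (-0.56) fell. The list was not called (median 0.22; camera, limma adjusted p = 0.0759) but passed with quantile normalization (0.0441), a minimum mean of 2 RPKM (0.0472) or no filter (0.0252), and 7 members rose without Luc replicate 1 and 6 without Sfpq replicate 2, while 1 fell without Sfpq replicate 1. Of 53 ribosomal protein genes, Rps12 (0.44), Rps25 (0.34) and Rpl4 (0.33) rose, Rpl7 (-1.30), Rps23 (-0.67) and Rpl15 (-0.53) fell and 47 did not pass (0 higher and 3 lower adjusted over the list alone with limma; 8 higher and 5 lower at unadjusted p under 0.05). Without Luc replicate 3, 7 ribosomal genes were higher and 8 lower, and the higher count was 5 without Luc replicate 2, 2 without Luc replicate 1, 1 without Sfpq replicate 1 or 2, and 0 without Sfpq replicate 3 or with median-ratio scaling (limma), but 8 with quantile normalization and 1 with no filter on low values. The ribosomal median was 0.11 (camera, limma adjusted p = 0.497), and these genes have many processed pseudogenes that can share reads.

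p53 targets and apoptosis genes went both ways, with 9 of 30 higher, 6 lower and 15 not past the test (9 and 6 adjusted over the list alone). The cell cycle inhibitor Cdkn1a (74.7 ± 9.66 to 30.2 ± 1.43 RPKM, SD, n = 3; -1.28) and Rrm2b (-0.90) fell, and Zmat3 (0.98) and the death receptor gene Fas (0.75) rose (median 0.19; camera, limma adjusted p = 0.537; 5 higher without Sfpq replicate 2). Immediate early genes, which respond within minutes to stimuli, had 5 of 27 higher, 5 lower and 17 not past the test, with the same counts adjusted over the list alone. Nr4a2 (1.04), Ier5 (0.84), Btg2 (0.60), Nr4a1 (0.54) and Arc (0.41) rose and Dusp6 (39.1 ± 1.14 to 19.3 ± 0.995 RPKM, SD, n = 3), Dusp1 (-0.71), Egr1 (-0.67), Myc (-0.52) and Atf3 (-0.40) fell, the 3 largest being fixed by rule and the others named after their values were seen. The immediate early median of 0.01 changed sign with median-ratio scaling (camera, limma adjusted p = 0.959), and 8 were higher without Luc replicate 2, 3 higher without Sfpq replicate 3 and 8 lower without Luc replicate 3.

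Markers of glia, fibroblasts, muscle, immune cells and endothelium were close to the floor, and 6 of 27 listed genes were expressed enough to test. The endothelial marker Pecam1 fell (1.43 ± 0.112 to 0.694 ± 0.102 RPKM, SD, n = 3; -0.69), 0 rose and 5 did not pass with limma (the same adjusted over the list alone; 1 higher and 1 lower at unadjusted p under 0.05). The marker median was -0.02 (camera, limma adjusted p = 0.87). Of the structural noncoding RNAs, 4 could be tested and none passed over all genes or adjusted over the list alone with limma (0 at unadjusted p under 0.05). Their most abundant member was Rmrp, at 29.98 ± 13.3 RPKM in Luc and 22.8 ± 3.59 in Sfpq libraries (SD, n = 3; limma adjusted p = 0.436), followed by Rpph1 at 1.28 ± 0.560 and 0.744 ± 0.486 RPKM (SD, n = 3; limma adjusted p = 0.216). Rmrp passed as lower without Luc replicate 3 (-0.66), 1 of 5 structural RNAs tested without Luc replicate 1 passed as lower, and 1 marker gene passed as higher without Luc replicate 3 or Sfpq replicate 1.

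**Figure D2:**
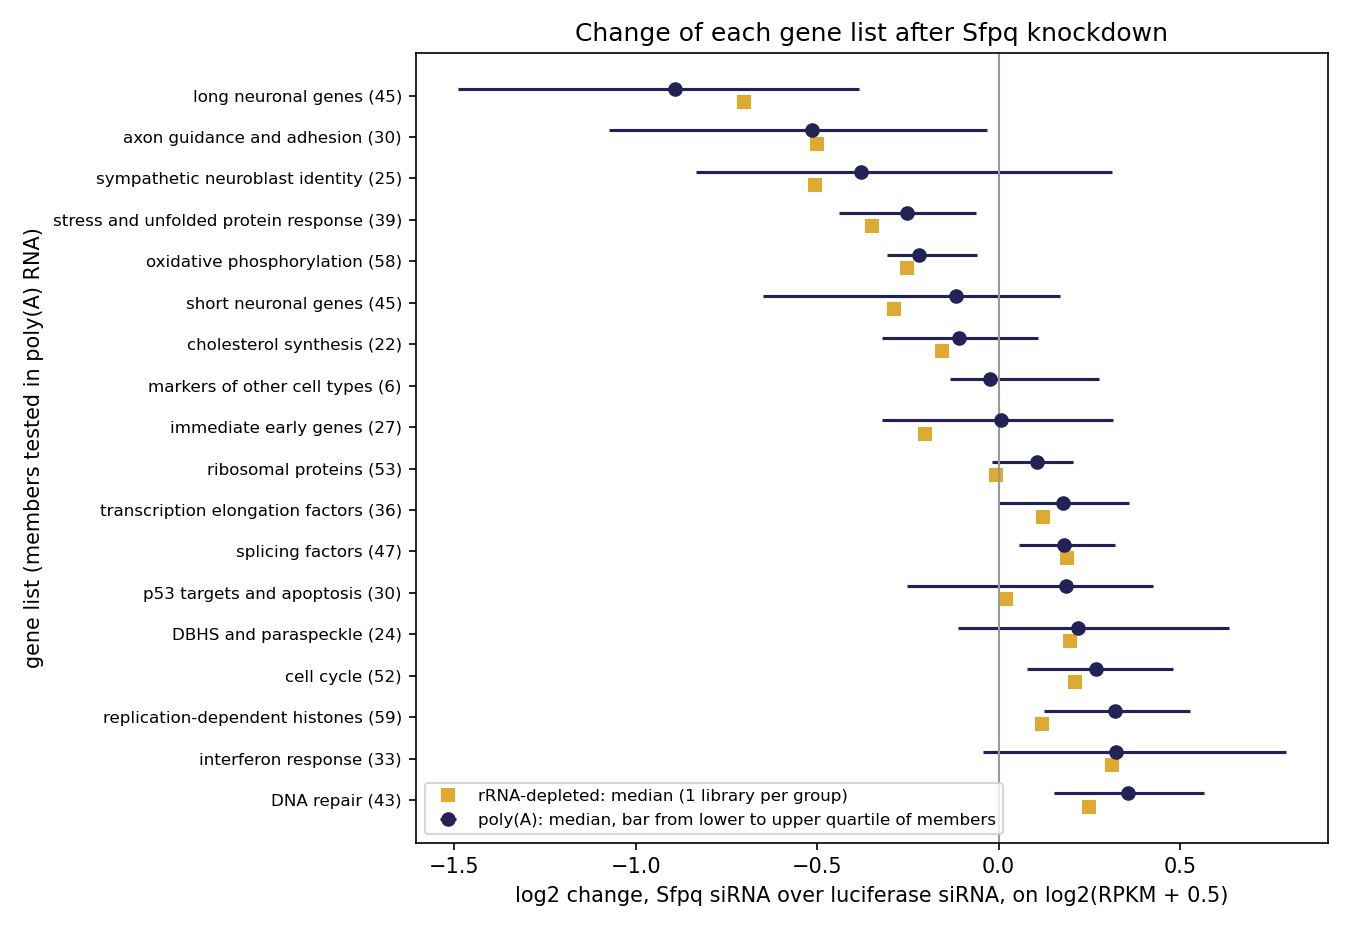
Median log2 change, Sfpq over Luc, of each planned gene list with at least 5 tested members (horizontal axis; number of members in parentheses); circles are poly(A) RNA with bars from the lower to the upper quartile of members, squares rRNA-depleted RNA with 1 library per group. Long neuronal genes had the lowest median in both preparations (-0.89 and -0.70), and DNA repair genes the highest of the planned lists in poly(A) RNA (0.36).

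The second comparison asks whether RNA prepared without poly(A) selection shows the same differences. In rRNA-depleted RNA, among genes with a mean of at least 5 RPKM there, the largest ratios were below 1 for Slc39a11 (log2 ratio -4.07), 3110082I17Rik (-4.01), Ergic1 (-3.91), Vat1l (-3.57) and the synapsin gene Syn2 (-3.23), and above 1 for NM_001081005 (2.05), Epb41l4aos (1.86), Taf1d (1.84), the matrix metalloproteinase gene Mmp15 (1.77) and Mgarp (1.76). Among the other genes with large changes in poly(A) RNA, Grap2 had a log2 ratio of 2.93, Mrtfb 1.23, Sfpq -2.67, Tmem150c -3.09, Clybl -2.26 and Rgs7 -3.28. Pspc1 (1.17) and Nono (0.44) were higher in the Sfpq library, while Neat1 (-0.14) and Malat1 (0.10) differed little. Chaserr was listed at 0 in both rRNA-depleted libraries and 1110038B12Rik at 0 and 0.0532 RPKM, so no ratio is given for them. With 1 library per group these differences have no replicate check.

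Across 11208 genes measured in both preparations, the poly(A) log2 fold change and the rRNA-depleted log2 ratio had a Pearson correlation of 0.938 and a Spearman correlation of 0.910; these are correlations across genes, which are not independent replicates. Of 2351 genes called higher in poly(A) RNA, 2316 (98.5%) were above 0 in rRNA-depleted RNA, and of 2123 called lower, 2118 (99.8%) were below 0. Among all genes in the rRNA-depleted table, 48.3% were above and 51.7% below 0. Among 535 genes that fell at least 2-fold in poly(A) RNA, 468 had a log2 ratio of -1 or lower. In all, 188 of 11386 genes had a ratio of 2 or more and 590 a ratio of 0.5 or less.

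**Figure D3:**
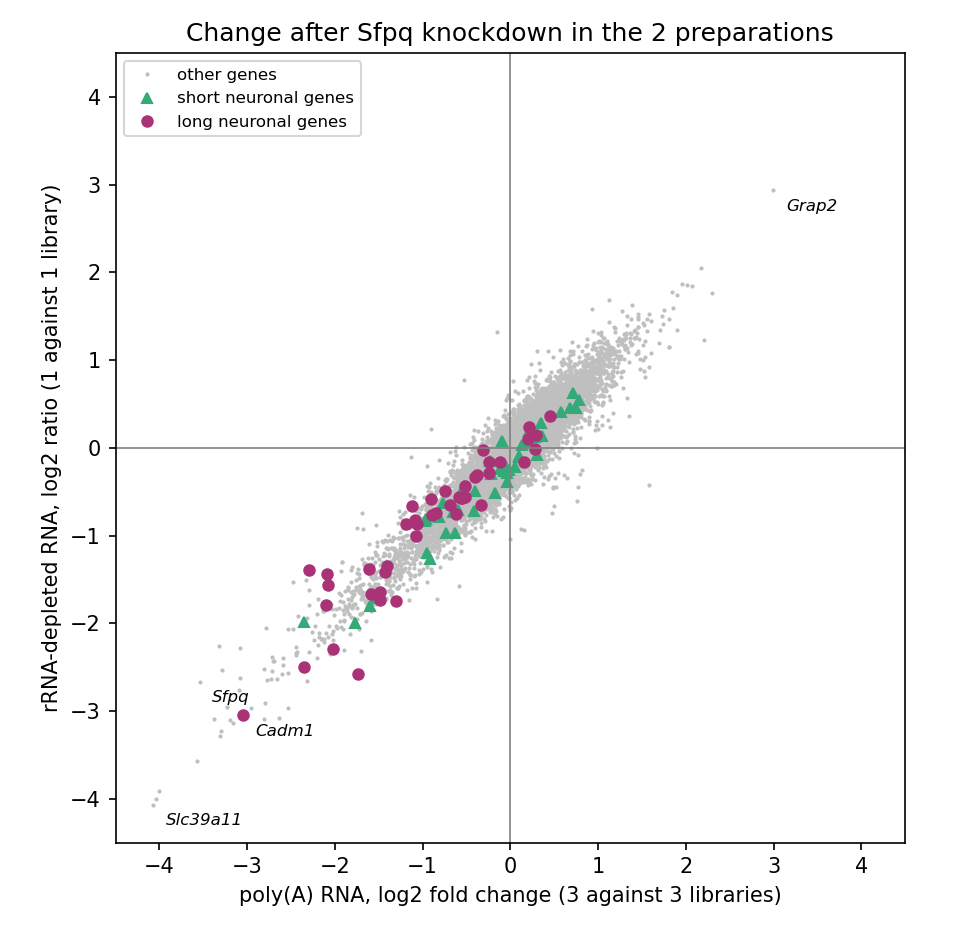
Log2 fold change in poly(A) RNA (horizontal axis, 3 against 3 libraries) against the log2 ratio in rRNA-depleted RNA (vertical axis, 1 against 1 library), both Sfpq over Luc; each point is 1 of 11208 genes. Points lie along the diagonal (Pearson correlation 0.938), with long neuronal genes such as Cadm1 (-3.05 and -3.04) towards the lower left.

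Long neuronal genes were again the lowest list. Of 44 measured in rRNA-depleted RNA, 40 had a log2 ratio below 0 and 4 above, with a median of -0.70, below all but 0.0% of 10000 random lists matched on expression (their central 95% ran from -0.16 to 0.18). The difference from the other genes was -0.69, and from the short neuronal genes -0.42. Cadm1 (-3.04), Ncam1 (-2.50), Mapt (-2.29) and Alk (-1.40) were among those below 0. Without the filter on low values the difference from other genes was -0.20.

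The other lists kept the sign of their poly(A) median in rRNA-depleted RNA, except immediate early genes (0.01 and -0.20) and ribosomal proteins (0.11 and -0.01). That sign was uncertain for some: bootstrap 95% intervals over members spanned 0 for p53 targets (-0.29 to 0.21), sympathetic identity (-0.99 to 0.28) and cholesterol synthesis genes (-0.37 to 0.04). Against random lists matched on expression, the ribosomal median lay above the central 95% in both preparations. That range was -0.21 to -0.003 in poly(A) RNA and -0.29 to -0.07 in rRNA-depleted RNA. The immediate early median lay within its range in both (-0.15 to 0.25 and -0.24 to 0.17). Their changes of sign therefore do not show a reversal. The structural RNA and marker lists rested on 3 genes each. Axon guidance genes had a median log2 ratio of -0.50, sympathetic identity genes -0.51, stress response genes -0.35, short neuronal genes -0.29 and oxidative phosphorylation genes -0.25. Interferon genes had 0.31, DNA repair genes 0.25 and cell cycle genes 0.21. The oxidative phosphorylation median lay within the central 95% of random lists matched on expression (-0.26 to -0.03, percentile 2.91). Of 52 cell cycle genes 36 lay above 0, as did 35 of 43 DNA repair and 22 of 31 interferon genes, and 36 of 39 stress response genes lay below. Replication-dependent histone genes, which had a median of 167 RPKM in the rRNA-depleted Luc library and 2.91 in poly(A) Luc libraries, had a median log2 ratio of 0.12, with 43 of 58 above 0. Rmrp took the highest level in both rRNA-depleted libraries, at 75042 RPKM in Luc and 42836 in Sfpq. The 10 highest genes held 35.5% of summed RPKM in the Luc and 29.5% in the Sfpq library there, against 7.31% to 7.98% in poly(A) libraries.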

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

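All tests in this part were chosen after the data were seen, and that of leaving out 1 Luc library for the histone list was set before its own value was seen. H1f2, a linker histone gene, is listed because all 3 Sfpq libraries lay above all 3 Luc libraries in poly(A) RNA (log2 fold change 1.58) while the rRNA-depleted Sfpq library lay below the Luc library, at 257 against 345 RPKM (log2 ratio -0.42). The difference between preparations was not tested, as the rRNA-depleted groups have 1 library each. Of 4474 called genes measured in both preparations, 38 had poly(A) groups that did not overlap and the opposite sign in rRNA-depleted RNA.

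Replication-dependent histones as a list had a median log2 fold change of 0.32 in poly(A) RNA (bootstrap 95% interval over members 0.24 to 0.42). More cells in S phase may raise them, and would raise them without poly(A) selection too, where the median was 0.12 (0.06 to 0.17). Random lists matched on expression had a central 95% of -0.28 to -0.07 there and of -0.07 to 0.23 in poly(A) RNA. The histone median lay above both ranges, and as these baselines differ, the raw medians cannot be compared directly. The smaller median thus bears little against S phase. Without Luc replicate 3 the poly(A) median was also 0.17 (0.06 to 0.29), which overlaps, and the interval covers members and not libraries. A Luc library with low histone values is a further candidate explanation, since the list's camera call ended without it (limma adjusted p = 0.172) although its median kept more than 50% of its size. The histone genes called by limma did not become fewer without that library (13 higher and 1 lower, against 12 and 0). Over all tested genes, however, the higher calls went from 2502 to 3621. With 1 rRNA-depleted library per group, these explanations cannot be told apart here, and an effect of Sfpq on histone mRNA ends stays open as untested.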

How the results depend on the processing

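The mean of all rows per gene and leaving out libraries for the correlation between preparations were tests chosen after the data were seen. Across the alternatives, Sfpq stayed lower and past the threshold (log2 fold change -3.40 to -3.71), and no call of a gene named by the rule changed direction. Of 1060 values for 71 such genes, 1032 kept their side of the threshold, 25 lost it and 3 gained it, among 8 genes. Genes named only after their values were seen are not in this count. Leaving out 1 library gave 1546 to 3621 higher and 1673 to 2645 lower genes, the 2 lowest higher counts being 1546 and 1631; fewer samples were then tested. Median-ratio scaling gave 2257 higher and 2504 lower genes (47.4% higher, against 53.4%). With an estimated correlation between genes, the long-minus-other difference of -0.95 no longer passed (camera p = 0.061), and 0 lists were called. Why the estimate had this effect was not tested. In rRNA-depleted RNA that difference was -0.86 with a pseudocount of 0.1 and -0.20 with no filter (bootstrap SD over genes 0.136). The correlation between preparations was 0.947 with a minimum mean of 2 RPKM, 0.912 with no filter, and 0.911 to 0.943 with 1 poly(A) library left out (bootstrap SD 0.00189, which covers genes only); the cause was not tested.

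Replicate numbers did not pair all the libraries. Same-numbered deviations correlated at 0.327 (the highest between a Luc and a Sfpq library), -0.035 and 0.157. Luc replicate 2 correlated best with Sfpq replicate 1, and Luc replicate 3 with Sfpq replicate 2 (0.166). A replicate block gave 2681 higher and 2309 lower genes and 10 called lists, without transcription elongation factors (camera, limma adjusted p = 0.0563), and Rpph1 then passed as lower (limma adjusted p = 0.0102). Spans of 50 and 200 kb were not run, for want of an annotation used here. With the spread of these libraries, simulated changes of 0.5 log2 units were recovered in 16.4% of cases; what depth limits was not tested.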

Other observations

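Noncoding host genes of small nucleolar RNAs (snoRNAs), whose introns hold RNAs that guide the modification of ribosomal RNA, were looked at because Epb41l4aos and Taf1d stood among the largest rises; their list and tests were chosen after that result was seen, while the test on decay factors was set before its values were seen. Of 15 measured in poly(A) RNA, 11 rose, 0 fell and 4 did not pass with limma (11 higher and 0 lower at unadjusted p under 0.05). Snhg12 rose from 70.9 ± 24.8 to 188 ± 5.68 RPKM (SD, n = 3; log2 fold change 1.45, limma adjusted p = 0.000481), Snhg7 by 1.34, Snhg6 by 1.28 and Snhg1 by 1.28 on the log2 scale, whereas Snhg3 had 17.1 ± 1.11 in Luc and 16.9 ± 1.98 RPKM in Sfpq libraries (SD, n = 3; limma adjusted p = 0.905). The list's median was 1.03 (camera p = 1.53e-05; p = 0.0347 with an estimated correlation), and as the list was prompted by its own members these values are not independent evidence.

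A candidate explanation of the host gene rise is an effect of poly(A) selection, but their median was 1.14 in rRNA-depleted RNA, where 12 of 12 measured genes lay above 0, in 1 library per group. Snhg3, Snhg9 and Snhg15 were below the filter of 0.5 RPKM there and are not among the 12. In poly(A) RNA, Snhg15 was called higher (log2 fold change 1.12), and Snhg3 and Snhg9 were not called. Slower nonsense-mediated decay, which removes many such host transcripts, may also raise the host genes. The pathway's own factors, which it limits through their mRNAs, had a median log2 fold change of 0.26, with Smg5 (1.07), Upf2 (0.70) and Upf1 (0.36) higher and Smg6 (-0.48) among those lower. A median over members that go both ways decides nothing, so decay stays open, as does transcription of the host genes, which was not tested.

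For the fall of long neuronal genes, weighed with tests chosen after the result was seen, low expression of the list alone may not account, since its poly(A) median lay at percentile 0.0 of 10000 random lists matched on mean RPKM. Poly(A) selection as the whole cause is argued against by the difference from other genes in rRNA-depleted RNA (-0.69), in 1 library per group; with no filter on low values it was -0.20, beside -0.19 in poly(A) RNA. A general fall of neuronal transcripts as the whole cause is argued against by the difference from short neuronal genes in poly(A) RNA (-0.78), although camera over both lists gave p = 0.196 with an estimated correlation. In rRNA-depleted RNA that difference was -0.42. The short list was itself lower there, with 31 of 43 genes below 0 and a median of -0.29, at percentile 0.24 of matched random lists. In poly(A) RNA its median of -0.12 lay within the central 95% of matched random lists (-0.14 to 0.14, percentile 4.3). Lower calls in poly(A) RNA made up 37.8% of the short list and 18.4% of genes outside the long list. A general fall as part of the cause therefore stays open. The gap between long and short lists was -2.30 ± 0.286 in Luc and -2.99 ± 0.0773 in Sfpq libraries (SD, n = 3; exact permutation p = 0.1, the smallest possible). An effect of Sfpq loss that grows with gene length remains a hypothesis, since no span was measured and the long list was less expressed than the short one (median 4.15 against 22.4 RPKM in Luc libraries).

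The 6 poly(A) libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05; 1 of them, the real one, called 4687 genes, and the highest count among the others was 0 with limma (859 at unadjusted p under 0.05, against 5774).

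Chaserr, a noncoding RNA next to the chromatin remodeller gene Chd2, was 1.78 ± 0.421 RPKM in Luc and 9.70 ± 0.301 in Sfpq libraries (SD, n = 3), while Chd2 was 3.62 ± 0.286 and 4.43 ± 0.399 (SD, n = 3; limma adjusted p = 0.108). Levels differed between preparations for some abundant genes: Gapdh had 1185 RPKM on average in poly(A) Luc libraries and 15.3 in the rRNA-depleted Luc library, and Actb 1009 and 1913. Of 7814 genes with a mean of at least 5 RPKM in poly(A) RNA, 15 were listed at 0 in both rRNA-depleted libraries.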
